A study of Arabidopsis thaliana with 18 samples.

How the data were processed

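RNA was profiled in 18 libraries from the male gametophyte of Arabidopsis thaliana Col-0, in 6 groups of 3 libraries. Of these, 12 libraries came from sorted nuclei of mature pollen: the vegetative cell (VC) and the sperm cells (SC) of the line labelled V-Mt and of WT. The other 6 came from late microspores (LMS), the uninucleate stage before the division that sets up both cell types. The V-Mt line carries REF6, a histone H3 lysine 27 demethylase, fused to GFP under the LAT52 promoter, which is active in the vegetative cell. Its other marker, under the HTR10 promoter, is a sperm histone fused to RFP, which the labels name HTR10 in the first pollen library and number upwards to HTR15 across the V-Mt pollen libraries. The WT pollen line carries HTR10 fused to RFP and histone H2B fused to GFP under an actin promoter, and the WT microspore line carries the RFP marker alone. Per the labels, nuclei were gated by GFP (VC) or RFP (SC) with a uniform side scatter, while microspores were gated by green autofluorescence with RFP-positive grains excluded. The GFP marker therefore differed between V-Mt VC and WT VC. Among microspores only the V-Mt line carried a GFP fusion, and whether this shifted the green gate was not tested. Per the labels, polyadenylated RNA was taken from sorted nuclei and total RNA from microspores, and both were amplified with a SMART-Seq kit. The labels give replicate numbers and do not say whether replicates came from separate plants, so p-values measure only the spread between these samples, which may be technical.

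The authors deposited FPKM values (fragments per kilobase of gene model, scaled to the fragments of the library) per gene and per isoform, as 4 tables. Per the submitters' processing notes, the tools were HISAT2 2.1.0, StringTie 1.3.5, Bowtie2 2.3.5 and RSEM 1.3.1 on TAIR10 for pollen nuclei; the notes for microspores list HISAT2 2.1.0, RSEM 1.3.1 and Bowtie2 with no version. Their settings, the treatment of multiply mapped reads and any scaling between libraries are not given in the sources used here. The pollen gene table holds 28424 entries, of which 25068 are AGI loci and 3356 are gene models without one, and the microspore table holds 24292. The 2 gene tables were deposited separately, so tests were run within each, and levels set side by side across them are not on a tested common scale. Isoform tables served only to check that gene and isoform FPKM sum alike (largest difference of column sums 0.99 in pollen and 0.34 in microspores). Gene names, coordinates and protein domain notes came from the TAIR10.1 reference annotation, which names 24862 of the 25068 pollen loci. In the microspore table, 2 stray lines of annotation text were left out.

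The files hold no read counts. The depth was estimated from the steps between low FPKM values of transcripts of at least 1200 bases, with an assumed fragment length of 250 bases, so the figures are estimates. They gave 9000000 to 24000000 fragments per pollen library and 1900000 to 3100000 per microspore library. Of the low values, 65.4% to 81.4% lay within 0.2 of a whole read across the 18 libraries, where an even spread would give 40%. The step of 1 read was set on the lowest of these same values, so this excess does not test the estimate. No count test was run. The precision of a single low FPKM value is poorest in microspores, where 1 fragment on a gene with an effective length of 1 kb is worth 0.325 to 0.539 FPKM.

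Groups were compared with limma 3.58.1 (trend model, R 4.3.3) on log2(FPKM + 1), so fold changes are on that scale and understate the change of low genes. Genes at 1 FPKM or more in at least 3 libraries of a table were tested. A gene can pass this filter through 1 group alone, and list counts cover the tested members only. A model with 1 mean per group was fitted over all 12 pollen libraries, whose groups then share 1 estimate of the spread, and a separate one over the 6 microspore libraries. The comparisons were V-Mt VC against WT VC, V-Mt SC against WT SC, WT SC against WT VC, V-Mt SC against V-Mt VC, the interaction (the V-Mt effect in VC minus that in SC) and V-Mt LMS against WT LMS. Tests were 2-sided, with Benjamini-Hochberg adjustment at 0.05. Groups, comparisons, gene lists, alternatives and the rule for named genes were fixed before the data were examined.

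The rule named, for V-Mt VC against WT VC, the 10 largest rises and 10 largest falls among nuclear genes past the threshold, with no overlap between the groups' libraries and a mean of at least 5 FPKM in the higher group. It took 5 each way for other comparisons, REF6, the marker histones (HTR10 and H2B genes), and up to 4 called members of each list, or 2 where none was called. Among genes with no effect, 10% of genes have no overlap between 3 and 3 libraries. The 14 lists, written from textbook knowledge, were sperm cell genes; pollen tube growth and signalling genes; vegetative cell wall and transporter genes; pollen MIKC* MADS, MYB and WRKY factors; Polycomb and H3K27 demethylase genes; developmental transcription factors known as Polycomb targets; DNA methylation genes; cell cycle genes; microspore and early pollen genes; tapetum and anther wall genes; photosynthesis genes; heat shock genes; egg and central cell genes; and histone variants. Of 268 members, 5 were left out because the reference annotation gives their locus another name (HTR10, TET11, DMP9, MSP2 and TIO). HTR10 is reported as the marker gene under its reference symbol, MGH3. Spelled-out synonyms counted as a match, a judgement made after the data were seen. Lists were tested with camera (limma, preset correlation 0.01), with an estimated correlation and with fry, adjusted over all lists and comparisons. A marker score per library, the mean log2(FPKM + 1) of the sperm list minus that of both vegetative lists, was compared by an exact 2-sided permutation test. Chance agreement between comparisons that share WT VC libraries was simulated with 100 draws of unchanged groups, and after the data were seen the class and the V-Mt effect were also computed on separate WT VC libraries. The text gives part of the genes that the rule names, and the others are not reported here.

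Size 4 was added to the simulated changes after low recovery at sizes 1 and 2 was seen. The fit was tested on simulated data over the same 19733 pollen genes, with known changes in genes above the lowest expression quartile. Changes of size 1 were given to 50 genes, of size 2 to 100 and of size 4 to 50. Where far more genes change, as in V-Mt VC, the adjusted threshold is less strict, so these shares are not the sensitivity there. In V-Mt VC against WT VC it recovered 0% of genes changed by 1 on the log2 scale, 32% of those changed by 2 and 80% of those changed by 4, with 9 false calls. False calls numbered at most 2 in the other comparisons. Recovery at sizes 1, 2 and 4 was 6%, 22% and 70% in V-Mt SC against WT SC, 2%, 26% and 80% in WT SC against WT VC, and 4%, 27% and 72% in V-Mt SC against V-Mt VC. For the interaction it was 0%, 7% and 48%. Over the 18002 microspore genes it was 0%, 3% and 32%. Alternatives were a pseudocount of 0.1, no filter or a filter at 5 FPKM, median-ratio scaling, quantile normalization, a block for the replicate number, array weights, a fit of the compared groups alone and leaving out each library. Genes enriched in 1 cell type of WT were those called at 2-fold or more, with 4-fold as the alternative. Added after the data were seen were a term for, and a fit without, the SC libraries with an organelle share of FPKM above 0.01%, and a block for the replicate number within each line. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 served for tables and figures.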

Results

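The libraries covered vegetative cell (VC) and sperm cell (SC) nuclei of mature pollen and whole late microspores (LMS), 3 each from V-Mt, in which the vegetative cell makes the H3K27 demethylase REF6, and from WT. Levels are given as mean FPKM ± SD (n = 3) and log2 fold changes with their standard error (SE). In V-Mt VC, 18863 ± 111 genes stood at 1 FPKM or more, against 8231 ± 147 in WT VC, 10361 ± 895 in V-Mt SC and 12271 ± 417 in WT SC. The microspores, whose table was normalized separately, held 16938 ± 70 (V-Mt) and 17790 ± 326 (WT). Estimated depth per library was 9300000 to 14100000 fragments in V-Mt VC, 16400000 to 24000000 in WT VC, 9000000 to 13600000 in V-Mt SC and 9200000 to 14500000 in WT SC, so V-Mt VC was not the deepest group. In microspores it was 2000000 to 3100000 fragments (V-Mt) and 1900000 to 2800000 (WT). Across genes, the rank correlation between libraries of a group was 0.946 to 0.947 in V-Mt VC, 0.834 to 0.908 in WT VC, 0.751 to 0.811 in V-Mt SC and 0.761 to 0.815 in WT SC. It was 0.643 to 0.684 within the microspore groups. V-Mt SC replicate 1 and WT SC replicate 3 correlated more closely with a library of another group (0.826 each) than within their own (at most 0.811 and 0.815). The same held for V-Mt LMS replicates 2 and 3 (0.7 and 0.675, within at most 0.673) and WT LMS replicates 1 and 2 (0.7 and 0.668, within at most 0.684 and 0.658). Chloroplast and mitochondrial genes took 0.0161% of FPKM in V-Mt SC replicate 3, 0.0432% in WT SC replicate 1 and 0.0731% in WT SC replicate 2, against at most 0.00118% in the other SC libraries.

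**Figure D1:**
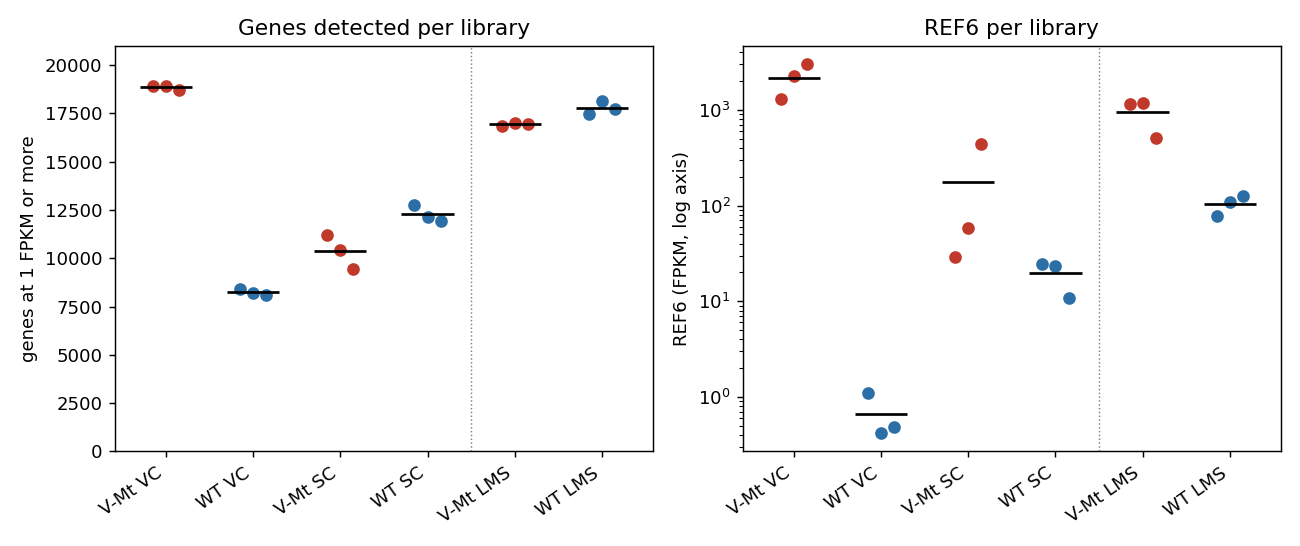
Genes at 1 FPKM or more (left) and REF6 in FPKM on a log axis (right) in each of the 18 libraries, with the black bar at the group mean and a dotted line between the pollen and microspore tables, which were normalized separately. The 3 V-Mt VC libraries lay between 18735 and 18932 genes and the 3 WT VC libraries between 8093 and 8386.

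The demethylase gene REF6 (AT3G48430) (chromosome 3, 17935256 to 17940792, TAIR10.1 annotation) stood at 2184 ± 851 FPKM in V-Mt VC and 0.667 ± 0.376 in WT VC, a log2 fold change of 10.30 (SE 0.82, limma adjusted p = 8.29e-07). In sperm nuclei the V-Mt libraries held 28.87, 58.4 and 436.38 FPKM and the WT libraries 24.55, 23.2 and 10.77, a difference that did not pass (log2 2.25, limma adjusted p = 0.131). REF6 was also higher in WT SC than in WT VC (log2 3.56, limma adjusted p = 0.00519), a call that was lost under 1 alternative (highest adjusted p 0.0536). Microspores of V-Mt held 1160.07, 1175.37 and 506.28 FPKM against 77.73, 108.15 and 124.86 in WT, and this log2 fold change of 3.11 (SE 0.37) did not pass (limma adjusted p = 0.193, 0.0552 to 0.961 over the alternatives). Reads of the REF6 transgene and of the endogenous gene cannot be told apart in these tables. The sperm histone gene MGH3 (AT1G19890), also named HTR10 and the source of the RFP marker, stood at 6014 ± 1991 FPKM in WT SC and 46.4 ± 13.3 in WT VC (log2 6.96, limma adjusted p = 3.64e-08), and at 10724 ± 1225 in V-Mt SC and 82.8 ± 7.8 in V-Mt VC (log2 7.00, limma adjusted p = 6.33e-09). Both pollen lines carry an RFP fusion of a sperm histone, labelled HTR10 in WT and in the first V-Mt library. Its reads cannot be told apart from those of endogenous MGH3, so these values are not levels of the endogenous gene alone. Its difference between V-Mt VC and WT VC was 0.85 (limma adjusted p = 0.0155) and turned to −0.23 with median-ratio scaling and −0.21 with quantile normalization. The H2B gene HTB8 (AT1G08170) was higher in WT SC too, at 691 ± 31.5 FPKM against 8.58 ± 0.0781 in WT VC. In WT pollen an H2B fusion to GFP marked VC, and whether its reads enter the values of H2B genes was not tested. HTB1 (AT1G07790), another H2B gene, was higher in VC than in SC in V-Mt. It stood at 92 ± 13.9 FPKM in V-Mt VC against 4.49 ± 7.35 in WT VC (log2 5.07, SE 1.34, limma adjusted p = 0.00553). In V-Mt SC it stood at 9.09 ± 11.3, lower than in V-Mt VC (log2 −4.08, limma adjusted p = 0.0183), a call lost without V-Mt VC replicate 2, V-Mt VC replicate 3 or V-Mt SC replicate 2 (highest adjusted p 0.0758). In WT it was higher in SC, at 61.2 ± 52.2 FPKM (log2 3.78, limma adjusted p = 0.0441), a call lost under 15 of 23 alternatives.

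Sperm and vegetative nuclei of WT give the normal difference between both cell types. Genes known for sperm cell function were far higher in WT SC: GEX2 (AT5G49150), a gamete membrane protein, stood at 289 ± 73.9 FPKM against 2.79 ± 0.549 in WT VC (log2 6.23, SE 0.30), DAN1 (AT3G04620) at 11109 ± 1261 against 152 ± 19 (log2 6.18, SE 0.13) and the zinc finger gene DAZ1 (AT2G17180) at 189 ± 106 against 0.807 ± 0.731 (log2 6.57, SE 0.58). Of 17 measured sperm cell genes 16 rose and 0 fell. Of 26 cell cycle and DNA replication genes 23 rose and 0 fell, among them the cyclin CYCD7;1 (AT5G02110) (13332 ± 4963 against 204 ± 57.8 FPKM, log2 6.0) and the mitotic kinase CDKB2;2 (AT1G20930) (349 ± 62.3 against 3.39 ± 1.02, log2 6.32). Pollen tube growth and signalling genes went the other way, with 25 of 32 lower in WT SC and 0 higher, and the receptor kinase PRK6 (AT5G20690) fell from 144 ± 40 FPKM in VC to 9.86 ± 7.87 in SC (log2 −3.97, SE 0.55). These 3 lists differed from other genes by camera (limma adjusted p = 6.1e-11, 8.52e-09 and 1.03e-13) and also with an estimated correlation (adjusted p = 0.0405, 0.00208 and 0.000528), with medians of 5.95, 4.14 and −2.50.

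Heat shock genes (8 of 12 rose, 0 fell, median 3.14) and DNA methylation genes (11 of 17 rose, 1 fell, median 2.32) were higher in WT SC as well. The small heat shock gene HSP17.4 (AT3G46230) stood at 719 ± 403 FPKM against 4.26 ± 3.5, and the maintenance DNA methyltransferase gene MET1 (AT5G49160) at 111 ± 12.2 against 2.21 ± 1.22 (log2 5.19, SE 0.29). Their camera tests passed (limma adjusted p = 0.00937 and 0.0169) and were lost with an estimated correlation (adjusted p = 0.337 and 0.318 with an estimated correlation). Of 18 vegetative cell wall and transporter genes 3 rose and 7 fell (median −1.01, mean −0.10, camera adjusted p = 0.045 by limma). That call was lost with an estimated correlation (adjusted p = 0.436 with an estimated correlation), and in turn without V-Mt SC replicate 2 (0.0554), WT VC replicate 2 (0.0589), WT VC replicate 3 (0.0529) or WT SC replicate 3 (0.0846). A member that rose was the tonoplast channel TIP5;1 (AT3G47440), at 5768 ± 238 FPKM in SC and 85.1 ± 16.1 in VC, so it does not mark the vegetative cell in these data. Tapetum and anther wall genes, markers of the surrounding tissue, did not pass (0 rose and 4 of 12 fell, limma adjusted p = 0.0536). This p came under 0.05 without any of 7 libraries in turn: V-Mt VC replicate 1 (0.0469), V-Mt VC replicate 3 (0.045), V-Mt SC replicate 1 (0.0497), WT VC replicates 1, 2 and 3 (0.0455, 0.0499 and 0.0416) and WT SC replicate 3 (0.0247).

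No other list passed by camera in this comparison. Pollen MADS, MYB and WRKY factors did with median-ratio scaling (limma adjusted p = 0.0158, 0 rising and 6 falling), and tapetum genes did with a pseudocount of 0.1 (limma adjusted p = 0.0362). Histone variant genes had 10 rising and 3 falling members of 19, photosynthesis genes 3 and 0 of 16, Polycomb genes 5 and 1 of 17, Polycomb target factors 4 and 0 of 22, pollen MADS, MYB and WRKY factors 1 and 3 of 9, microspore genes 1 and 3 of 7, and egg and central cell genes 0 and 0 of 3. The balance of Polycomb genes turned to 3 rising and 5 falling with median-ratio scaling and 2 and 6 with quantile normalization. That of target factors turned to 2 and 5 with quantile normalization. The Polycomb group gene FIS2 (AT2G35670) rose (293 ± 88.3 against 1.94 ± 0.572 FPKM, log2 6.62), while VIN3 (AT5G57380) fell (23 ± 20.6 against 307 ± 44.2, log2 −4.03) and the pollen factor AGL65 (AT1G18750) fell (47.4 ± 47.3 against 833 ± 208, log2 −4.53). Outside the lists the largest rises included AT5G28380, a tetratricopeptide repeat protein (log2 8.18, SE 0.51), the RNA-binding protein gene GRP7 (AT2G21660) (7.48, SE 0.68) and the cyclophilin gene ROC3 (AT2G16600) (7.35, SE 0.40), and the largest falls the small GTPase genes ArRABA1h (AT2G33870) (−6.66, SE 1.44) and ARLA1B (AT3G49860) (−6.61, SE 1.28). In all, 7981 of 19733 genes passed in limma, 5390 higher and 2591 lower in SC. The higher share was 67.5%, 52.7% with median-ratio scaling and 45.8% with quantile normalization, and the median of all genes was 0.36, 0.07 and −0.06. Counts adjusted over the list alone were the same except for cell cycle genes (24 rose) and vegetative wall genes (3 rose and 9 fell).

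**Figure D2:**
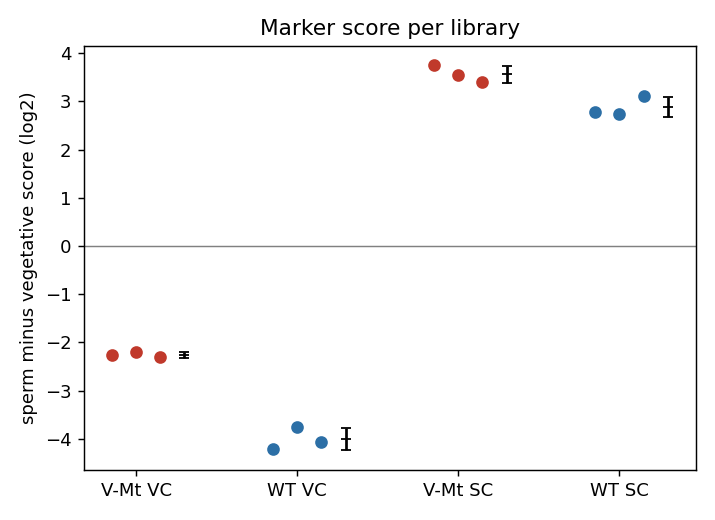
Marker score of each pollen library, the mean log2(FPKM + 1) of sperm cell genes minus that of both vegetative lists, with the black mark and bars at the group mean ± SD (n = 3) and a grey line at 0. V-Mt VC libraries lay at −2.26 ± 0.06, between WT VC at −4.01 ± 0.24 and both sperm groups, at 3.56 ± 0.18 (V-Mt) and 2.88 ± 0.21 (WT), with most of its difference from WT VC in the vegetative lists, whose mean fell by 1.50.

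V-Mt VC against WT VC asks which transcripts differ where REF6 is made. Genes of pollen tube growth and signalling fell together: 24 of 32 fell and 0 rose, with a median of −2.97. The calcium-dependent kinase CPK34 (AT5G19360) fell from 646 ± 138 FPKM in WT VC to 9.07 ± 0.79 in V-Mt VC (log2 −5.99, SE 0.85), the receptor kinase BUPS1 (AT4G39110) from 826 ± 24.5 to 35.1 ± 4.74 (log2 −4.52, SE 0.24) and the wall protein LRX8 (AT3G19020) from 1125 ± 639 to 26.7 ± 3.92 (log2 −5.22, SE 0.38). Against other genes the list stood apart by camera (limma adjusted p = 4.96e-22) and with an estimated correlation (adjusted p = 0.000236). The falls held under both other scalings, with 0 rising and 31 falling members (median-ratio) and 1 rising and 24 falling (quantile).

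Among the largest falls outside the lists, AT5G27870, a pectin methylesterase inhibitor family member, fell from 1684 ± 129 to 4.51 ± 1.69 FPKM (log2 −8.31, SE 0.89), SEC14 (AT4G39180), a lipid transfer protein gene, from 10432 ± 1707 to 60.4 ± 12.4 (−7.42, SE 0.76), the expansin EXPB5 (AT3G60570) from 1197 ± 354 to 7.37 ± 1.55 (−7.13, SE 0.60) and pyruvate orthophosphate dikinase PPDK (AT4G15530) from 2347 ± 723 to 13.7 ± 5.37 (−7.33, SE 0.85). Among the largest rises, AT5G20290 (ribosomal protein S8e) stood at 4402 ± 336 FPKM in V-Mt VC and 1.15 ± 0.486 in WT VC (log2 11.02, SE 0.62), STV1 (AT3G53020) (L24e) at 1885 ± 89.1 and 0.14 ± 0.171 (10.70, SE 0.39), RPL5B (AT5G39740) at 1139 ± 38.5 and 0.36 ± 0.125 (9.71, SE 0.41) and AT1G67430 (L22p/L17e) at 2053 ± 100 and 0.3 ± 0.052 (10.63, SE 0.72). AT2G07640 stood at 1043 ± 91.7 FPKM in V-Mt VC and was listed at 0 in all 3 WT VC libraries. Ribosomal protein, RBCS, actin and histone genes have near-identical copies whose reads the authors' counting could split, so their single values are uncertain.

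Polycomb and H3K27 demethylase genes had 13 rising and 2 falling members of 17, REF6 among the first (median 3.76). FIS2 rose from 1.94 ± 0.572 to 939 ± 91.9 FPKM (log2 8.34, SE 0.25), EMF1 (AT5G11530) from 1.22 ± 0.34 to 85.2 ± 6.05 (5.29, SE 0.36) and EMF2 (AT5G51230) from 1.06 ± 1.06 to 72.7 ± 3.91 (5.28, SE 0.51). Of 22 developmental transcription factor genes known as Polycomb targets 17 rose and 0 fell (median 2.34): the homeobox genes KNAT2 (AT1G70510) (68.3 ± 12.7 against 0.0433 ± 0.0513 FPKM, log2 6.04) and KNAT6 (AT1G23380) (log2 5.57), and SEP3 (AT1G24260) at 19.3 ± 3.21 in V-Mt VC and listed at 0 in all 3 WT VC libraries. These 22 are the members, of 30 listed, that passed the filter. A member low in WT VC could pass it through V-Mt VC alone, and near 0 there it could hardly fall. Against all genes, whose median rose by 1.92 on the log2 scale, neither list stood apart by camera (limma adjusted p = 0.384 and 0.106). Without WT VC replicate 1 the p of the target factors was 0.0492. With quantile normalization, where the median of all genes was −0.02, 8 Polycomb members rose and 4 fell, and 7 target factors rose and 3 fell.

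Sperm cell genes moved both ways in V-Mt VC, with 4 of 17 rising and 6 falling. This balance was 3 and 10 with median-ratio scaling and 2 and 14 with quantile normalization. DAN1 rose from 152 ± 19 to 3289 ± 178 FPKM (log2 4.43, SE 0.13) and the sperm regulator DUO1 (AT3G60460) from 1.17 ± 0.779 to 35 ± 2.26 (4.13, SE 0.48), while the fertilization factor GCS1 (AT4G11720) rose by 2.73 (SE 0.39) and stood at −0.22 with quantile normalization. GEX3 (AT5G16020), another gamete membrane protein gene, fell from 7.03 ± 0.634 to 2.08 ± 0.689 FPKM (log2 −1.41, SE 0.34), and GEX1 (AT5G55490), GEX2, DAZ3 (AT4G35700), PCR11 (AT1G68610) and DAF1 (AT3G62230) fell too. The median was −0.52, the mean 0.25 and the camera direction downward relative to other genes (limma adjusted p = 0.00581), a call lost with an estimated correlation (adjusted p = 0.326 with an estimated correlation). Vegetative cell wall and transporter genes also split, with 7 of 18 rising and 8 falling (median −0.55, mean 0.91). The sugar transporter gene SWEET8 (AT5G40260) rose from 1.92 ± 1.49 to 722 ± 91.3 FPKM (log2 8.07, SE 0.56) and STP2 (AT1G07340) from 0.08 ± 0.0608 to 102 ± 8.61 (6.57, SE 0.56), while STP11 (AT5G23270), SWEET5 (AT5G62850), CHX23 (AT1G05580), VGDH1 (AT2G47030), CHX21 (AT2G31910), PPME1 (AT1G69940), SPIK (AT2G25600) and AHA8 (AT3G42640) fell. The camera call of this list (limma adjusted p = 0.00223) was lost with an estimated correlation (adjusted p = 0.318 with an estimated correlation). SWEET8 and STP2 were low in WT VC, so they do not mark the vegetative cell in these data.

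Microspore and early pollen genes had 2 rising and 4 falling members of 7 (median −1.11): MYB81 (AT2G26960) rose by 5.04 and BZIP34 (AT2G42380) fell from 109 ± 19.9 to 9.08 ± 0.286 FPKM (log2 −3.43, SE 0.68). Camera passed (limma adjusted p = 0.0363) and missed with an estimated correlation (adjusted p = 0.211 with an estimated correlation), and without V-Mt VC replicate 2 (0.0503) or replicate 3 (0.0648). Of 17 DNA methylation genes 10 rose and 2 fell, with the Argonaute gene AGO4 (AT2G27040) rising from 0.0333 ± 0.0416 to 302 ± 12 FPKM (log2 8.19, SE 0.58). Of 26 cell cycle genes 11 rose and 4 fell, among the risers CYCD4;1 (AT5G65420) (145 ± 19 against 10.3 ± 5.92 FPKM). Heat shock genes had 10 rising and 0 falling members of 12 (median 2.84), with HSP90.1 (AT5G52640) at 81.9 ± 8.48 against 2.31 ± 0.728 FPKM, and histone variant genes 12 and 1 of 19 (median 2.3), with HTR6 (AT1G13370) at 200 ± 26.3 against 0.09 ± 0.156. None of these 4 lists stood apart by camera (limma adjusted p = 0.903, 0.179, 0.462 and 0.896), and with quantile normalization DNA methylation genes had 6 rising and 5 falling members (median −0.57) and cell cycle genes 2 and 13 (median −1.21).

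Most measured markers of other tissues rose in V-Mt VC, as did 62.5% of all tested genes. Measured were 16 of 18 listed photosynthesis genes, 12 of 20 tapetum and anther wall genes and 3 of 9 egg and central cell genes. Members low in WT VC could pass the filter through V-Mt VC alone and could hardly fall. Photosynthesis genes had 12 rising and 1 falling member of 16, with rubisco activase RCA (AT2G39730) at 20 ± 1.22 against 0.00667 ± 0.0115 FPKM. Tapetum and anther wall genes had 9 and 3 of 12, with MS2 (AT3G11980) at 27.2 ± 4.52 against 0.157 ± 0.0709, and egg and central cell genes 2 and 0 of 3, with the imprinted gene FWA (AT4G25530) at 77.9 ± 5.63 against 0.75 ± 0.314. Pollen MADS, MYB and WRKY factors had 3 rising (AGL94 (AT1G69540) by 4.76) and 3 falling members (AGL65 from 833 ± 208 to 101 ± 19.9 FPKM) of 9. These 4 lists did not stand apart by camera (limma adjusted p = 0.776, 0.776, 0.942 and 0.0748), and for tapetum genes the camera direction was downward while the median was 1.79. The pollen factors passed with median-ratio scaling (limma adjusted p = 0.0194, camera downward, 2 rising and 4 falling). With quantile normalization photosynthesis genes had 2 rising and 4 falling members, tapetum genes 1 and 4 and egg and central cell genes 1 and 1. Counts adjusted over the list alone were the same in this comparison except for sperm cell genes (4 rose and 3 fell) and Polycomb genes (14 rose and 2 fell).

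**Figure D3:**
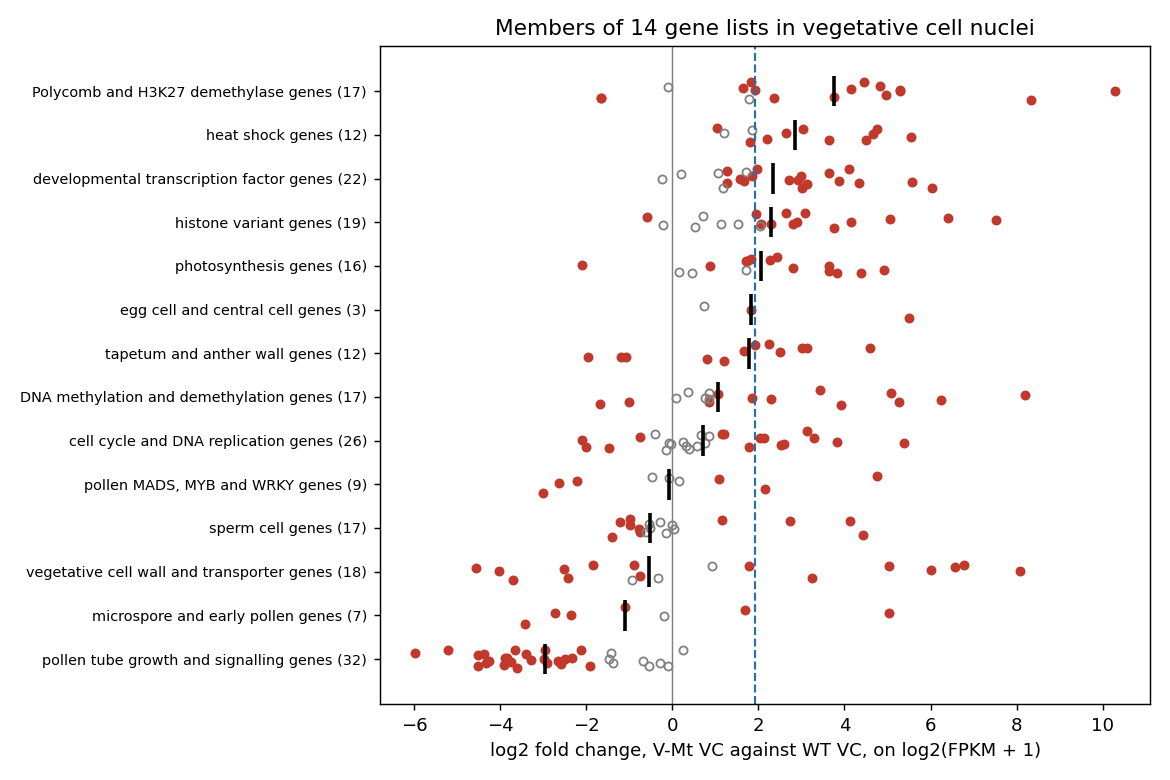
Log2 fold change of each measured member of 14 gene lists in V-Mt VC against WT VC, on log2(FPKM + 1), with limma adjusted p under 0.05 in filled red and others in open grey. Black bars mark list medians and the blue dashed line the median of all genes, 1.92; the pollen tube list has the lowest median, −2.97.

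In all, 14456 of 19733 genes passed in limma, 12334 higher and 2122 lower in V-Mt VC. Gene models without an AGI identifier made up 2628 of the tested genes, of which 2214 rose and 99 fell. The higher share was 85.3%, 77% with median-ratio scaling and 52.4% with quantile normalization, where 5770 genes rose and 5244 fell. Of the 8533 genes called both ways, 680 had the opposite sign with quantile normalization, so the direction of these 680 genes depends on the scaling.

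Genes that differ between the cell types of WT moved unevenly in V-Mt VC. Of 5294 genes at least 2-fold higher in WT SC, 3589 (67.8%) rose in V-Mt VC and 195 (3.68%) fell, against 62.5% and 10.8% of all genes. Of 2492 genes at least 2-fold higher in WT VC, 336 (13.5%) rose and 1292 (51.8%) fell. Independent lists of these sizes would share 3309 rises and 569 falls in the first class, and 1558 rises and 268 falls in the second. Over the sperm-enriched class the median log2 difference from WT SC was −0.84 in V-Mt VC, and 1978 of its genes stood at or above the WT SC level there. In WT VC it was −3.17, a value set in part by the choice of the class on these libraries. Among the 100 most abundant sperm-enriched genes 43 rose and 31 fell. Both comparisons share the WT VC libraries. Simulated unchanged groups gave 0 rises and 0 falls in the first class and 0 rises and 0.01 falls in the second. Unchanged groups pass for almost no gene, so these counts do not measure what the shared libraries add where real effects exist. Across genes, which are not independent replicates, the log2 fold changes had a covariance of 2.18 against 0.186 in simulation (Pearson r 0.414 against 0.141). The controls were also split, a step chosen after the data were seen, so that 1 WT VC library served for the class and the other 2 for the V-Mt effect, or the reverse. Over the 6 assignments 56.7% to 66.2% of sperm-enriched genes rose and 2.56% to 5.41% fell, against 52.7% to 59.7% and 7.81% to 10.2% of all genes. Of VC-enriched genes 10% to 20.6% rose and 43% to 57.3% fell. Each of the 4 shares lay on the same side of the share of all genes in all 6, and the covariance was 2.00 to 2.21. The median difference of sperm-enriched genes from WT SC was then −1.48 to −1.04 in V-Mt VC and −3.90 to −3.40 in the WT VC libraries not used for the class. The split does not remove the level in WT VC, which sets the classes, and a gene near 0 there can hardly fall. Among tested nuclear genes under 1 FPKM in WT VC, 83.7% of those at 10 FPKM or more in WT LMS rose. Of those under 1 FPKM in WT LMS 70.1% rose. Genes low in WT VC can pass the filter on low values through V-Mt VC alone, which raises both shares. Without that filter the shares were 71.3% and 49.7%. Classes were not compared with genes of like WT VC level, so these shares do not tell class from level.

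The marker score of V-Mt VC lay above that of WT VC by 1.75 in log2 units, with a change of 0.25 in the mean of sperm cell genes and −1.50 in that of both vegetative lists. The sperm mean changed by −0.60 with median-ratio scaling and −1.50 with quantile normalization, and the vegetative mean by −2.52 and −2.30. Without these scalings the pollen tube list had a mean change of −2.85 and the wall and transporter list one of 0.91. The higher score thus reflects the fall of pollen tube genes. V-Mt SC lay above WT SC by 0.69, with changes of −0.05 in the sperm mean (0.47 and 0.02 with these scalings) and −0.73 in the vegetative mean. Sperm nuclei lay above vegetative nuclei by 6.88 in WT and 5.82 in V-Mt. In each of these comparisons the 3 and 3 libraries had no overlap, and the exact 2-sided permutation p was 0.1, the smallest that 3 against 3 allows.

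Sperm nuclei of V-Mt against its own vegetative nuclei give the cell-type difference within the line. Of 17 sperm cell genes 16 rose and 0 fell (median 6.08): DAF1 stood at 55183 ± 6997 FPKM in V-Mt SC and 356 ± 69.8 in V-Mt VC (log2 7.28, SE 0.25), DAZ3 at 14182 ± 839 and 69.5 ± 13.8 (7.67, SE 0.27) and GEX3 at 536 ± 52.7 and 2.08 ± 0.689 (7.47, SE 0.34). Of 26 cell cycle genes 17 rose and 4 fell (median 3.53), with CYCD7;1 at 13159.5 ± 178 against 70.6 ± 5.87 FPKM and the replication licensing gene CDC6 (AT2G29680) at 98.3 ± 33.8 against 0.87 ± 0.46. Both lists stood apart by camera (limma adjusted p = 2.96e-16 and 6.1e-11) and with an estimated correlation (adjusted p = 0.0133 and 0.00114). HTB8 was higher in SC (log2 7.35) and REF6 was lower (log2 −4.49, SE 0.82).

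Polycomb genes had 1 rising and 14 falling members of 17 (median −2.60), with EMF2 at 0.06 ± 0.0557 against 72.7 ± 3.91 FPKM and EMF1 at 1.1 ± 0.839 against 85.2 ± 6.05. Target factors had 1 and 17 of 22 (median −1.71), with KNAT2 at 0.06 ± 0.104 against 68.3 ± 12.7 and the exception BBM (AT5G17430) higher in SC (85.2 ± 15.6 against 2.32 ± 1.08). With quantile normalization 3 target factors rose and 6 fell. AGO4 stood at 0.693 ± 0.307 FPKM in SC against 302 ± 12 in VC, and AT2G07640 at 0.253 ± 0.23 against 1043 ± 91.7. Neither list passed by camera (limma adjusted p = 0.282 and 0.179). Pollen tube genes, with 5 rising and 11 falling members of 32, had a median of −0.39 and an upward camera direction (limma adjusted p = 0.0644). With median-ratio scaling the list passed upward (limma adjusted p = 0.00948), with 9 rising and 7 falling members and a median of 0.06. Quantile normalization gave 14 and 8 (median 1.15). The wall protein gene LRX11 (AT4G33970) was higher in SC (161 ± 41 against 12 ± 2.44 FPKM) and the actin gene ACT11 (AT3G12110) lower (22.1 ± 7.12 against 272 ± 42.2).

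The other 9 lists did not pass by camera here. Histone variant genes had 2 rising and 11 falling members of 19, DNA methylation genes 6 and 8 of 17, tapetum genes 0 and 9 of 12, vegetative wall genes 3 and 8 of 18, photosynthesis genes 2 and 8 of 16, heat shock genes 1 and 4 of 12, microspore genes 1 and 3 of 7, pollen MADS, MYB and WRKY factors 1 and 4 of 9 and egg and central cell genes 0 and 2 of 3. Quantile normalization left tapetum genes with 1 rising and 2 falling members and microspore genes with 2 and 2. It turned photosynthesis genes to 3 and 2, heat shock genes to 3 and 1 and DNA methylation genes to 8 and 4 (8 and 7 with median-ratio scaling). The largest rises outside the lists included the zinc finger gene AT4G35610 (6908 ± 166 against 24.9 ± 4.15 FPKM, log2 8.07) and AT5G05510, which carries a Mad3/BUB1 region (3840.3 ± 547 against 16.1 ± 2.65, log2 7.81). The largest falls included AT2G42480, a MATH domain protein (2.51 ± 1.51 against 1169 ± 70.6, log2 −8.50) and FKBP53 (AT4G25340), an FK506-binding protein (0.807 ± 0.681 against 556 ± 339, log2 −8.17). In limma 14090 of 19733 genes passed, 2650 higher and 11440 lower in SC. The higher share was 18.8%, 22.4% with median-ratio scaling and 44.7% with quantile normalization, and the median of all genes was −1.72, −1.35 and −0.04. Counts adjusted over the list alone were the same except for cell cycle genes (18 rose) and pollen tube genes (5 rose and 9 fell).

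In sperm nuclei, where REF6 did not pass, V-Mt and WT differed less. Pollen tube genes had 7 falling and 0 rising members of 32 (17 fell when adjusted over the list alone) and a median of −1.17. There were 2 falling members with median-ratio scaling (median −0.68) and 5 with quantile normalization (median −0.67). BUPS1 stood at 100 ± 26.9 FPKM in V-Mt SC and 300 ± 62.6 in WT SC (log2 −1.59, SE 0.24, limma adjusted p = 0.0118) and ACT11 at 22.1 ± 7.12 and 147 ± 69.7 (−2.58, SE 0.38, limma adjusted p = 0.011). The list stood apart by camera (limma adjusted p = 4.55e-06) and with an estimated correlation (adjusted p = 0.00572). In WT 25 of these 32 genes were lower in SC than in VC, and 24 fell in V-Mt VC. Whether VC RNA carried into the sperm sorts gives part of their level here was not tested. Histone variant genes had 4 falling and 0 rising members of 19 (10 fell and 1 rose when adjusted over the list alone; median −1.35), with HTR5 (AT4G40040) at 115 ± 15.9 against 260 ± 84.8 FPKM (log2 −1.12, limma adjusted p = 0.0322). The HTR5 call was lost under 13 of 22 alternatives (highest adjusted p 0.411). The camera call of the list (limma adjusted p = 0.00815) was lost with an estimated correlation (adjusted p = 0.358 with an estimated correlation). With median-ratio scaling 1 histone gene rose and 1 fell, and with quantile normalization 0 rose and 1 fell. The pectin methylesterase gene VGDH1 fell as well, from 540 ± 145 to 148 ± 31 FPKM, and RBCS3B (AT5G38410) rose from 902 ± 235 to 1979 ± 162, a call lost under 4 of 22 alternatives (highest adjusted p 0.378).

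Among the largest changes, AT1G19600 stood at 76.7 ± 84.6 FPKM in V-Mt SC and 0.0967 ± 0.106 in WT SC (log2 5.45, SE 0.70, limma adjusted p = 0.00688), AT3G07568 at 0.137 ± 0.237 against 43.7 ± 27.9 (−5.05, SE 0.58, limma adjusted p = 0.00641), and ENODL21 (AT5G14345) at 101 ± 96.1 in WT SC and listed at 0 in all 3 V-Mt SC libraries. The sperm list had 1 falling member of 17, DAZ2 (AT4G35280) (log2 −1.60, limma adjusted p = 0.0443), a call lost under 19 of 22 alternatives (highest adjusted p 0.537). The list did not pass (limma adjusted p = 0.114; 0.0328 without WT SC replicate 3). With median-ratio scaling it passed upward (limma adjusted p = 0.00948), with 2 rising and 0 falling members and a median of 0.67. Quantile normalization gave 0 and 0. Heat shock genes had 0 called members of 12 (1 rose and 4 fell when adjusted over the list alone; limma adjusted p = 0.0644), with limma adjusted p = 0.0492 without WT VC replicate 1, 0.047 without WT SC replicate 2 and 0.0247 without WT SC replicate 3. Of the remaining lists, vegetative wall genes had 1 rising and 3 falling members, photosynthesis genes 1 and 1, and cell cycle, DNA methylation, microspore, Polycomb and pollen MADS, MYB and WRKY genes 1 falling member each. Polycomb targets, tapetum genes and egg and central cell genes had none, and no remaining list passed. Adjusted over the list alone, cell cycle genes had 2 rising and 1 falling member, microspore genes 0 and 2, vegetative wall genes 2 and 4 and pollen MADS, MYB and WRKY genes 1 and 2. With median-ratio scaling, over all genes, cell cycle genes had 2 rising and 0 falling members and vegetative wall genes 2 and 1.

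In limma 1008 of 19733 genes passed, 232 higher and 776 lower in V-Mt SC, and 4641 had an unadjusted p under 0.05. This count rests on the spread shared with the VC libraries: a fit of the 6 sperm libraries alone called 0 genes (2035 with an unadjusted p under 0.05), where the named genes had adjusted p of 0.378 or more, and weights per library left 34. It was 347, 322 and 379 without V-Mt VC replicate 1, 2 or 3, 390 and 384 without WT VC replicate 2 or 3, 517 without WT SC replicate 1 and 3296 without WT SC replicate 3. Parting the 6 sperm libraries by organelle share, with V-Mt SC replicates 1 and 2 and WT SC replicate 3 on 1 side, called 1077 genes. The count was 1087 with a term for that share and 742 without the 3 high libraries, both chosen after the data were seen. The higher share was 23%, 49.9% with median-ratio scaling and 47.2% with quantile normalization.

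The interaction tests whether the V-Mt effect differed between both nuclei. REF6 differed by 8.05 (SE 1.15, limma adjusted p = 0.000124), FIS2 by 8.24 (SE 0.35), SWEET8 by 8.72 (SE 0.79), AGO4 by 10.57 (SE 0.83) and DAN1 by 4.08 (SE 0.18), each higher in VC relative to SC. Pollen tube genes had 18 members with a lower and 1 with a higher effect in VC of 32 (median −2.10), with LRX11 at −3.94 (SE 0.45) and PRK6 at −3.92 (SE 0.78), and the list stood apart by camera (limma adjusted p = 5.95e-17) and with an estimated correlation (adjusted p = 0.000333). Sperm cell genes (3 higher and 5 lower of 17, median 0.12, camera downward) and vegetative wall genes (6 higher and 4 lower of 18, median −0.19, mean 1.05, camera downward) passed by camera (limma adjusted p = 0.0032 for each). Both calls were lost with an estimated correlation (adjusted p = 0.318 and 0.326 with an estimated correlation). Sperm cell genes had 2 higher and 9 lower with median-ratio scaling (median −1.37) and 1 and 10 with quantile normalization (median −1.76). Vegetative wall genes had 5 and 10 with the first and 4 and 7 with the second.

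Of the other lists, histone variant genes had 17 higher and 1 lower of 19, target factors 17 and 0 of 22, Polycomb genes 13 and 1 of 17, photosynthesis genes 12 and 0 of 16, cell cycle genes 11 and 5 of 26, heat shock genes 10 and 0 of 12 and DNA methylation genes 10 and 1 of 17. Tapetum genes had 6 and 3 of 12, pollen MADS, MYB and WRKY factors 3 and 1 of 9, microspore genes 2 and 2 of 7 and egg and central cell genes 1 and 0 of 3. None passed by camera in limma, and the p of cell cycle genes was 0.0644, or 0.0492 without WT VC replicate 1. With median-ratio scaling cell cycle genes (limma adjusted p = 0.0288, 5 higher and 6 lower) and pollen MADS, MYB and WRKY factors (limma adjusted p = 0.0303, 2 and 4) passed, both downward. With quantile normalization 4 target factors were higher and 4 lower, 3 photosynthesis genes higher and 3 lower, and 1 cell cycle gene higher and 12 lower. In the same setting DNA methylation genes had 5 higher and 4 lower (median −0.10, against 2.42 before), Polycomb genes 7 and 4, tapetum genes 0 and 4, microspore genes 0 and 3 and pollen MADS, MYB and WRKY factors 2 and 4. Adjusted over the list alone, 11 heat shock genes were higher, and pollen MADS, MYB and WRKY factors had 2 higher and 1 lower, with no change in the other lists. In limma 13351 of 19733 genes passed, 11935 higher and 1416 lower. The higher share was 89.4%, 78.8% with median-ratio scaling and 51.8% with quantile normalization, and the median of all genes was 2.24, 1.52 and 0.02.

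Late microspores of both lines were compared, the stage before the vegetative cell exists. Whether later grains entered these sorts was not tested, and MGH3 ranged from 0 to 48.83 FPKM in V-Mt. The green gate of the sort could also differ between the lines, since the WT microspore line carried no GFP fusion. REF6 was higher in each V-Mt library there (506.28 to 1175.37 against 77.73 to 124.86 FPKM) without passing. No gene passed in limma (0 of 18002, with 1195 at an unadjusted p under 0.05), and simulated changes of 4 on the log2 scale were recovered in 32% of genes. The flower factor SEP2 (AT3G02310) stood at 19.4 ± 18.9 FPKM in V-Mt and 107 ± 17.8 in WT (log2 −2.84, limma adjusted p = 0.618), DUO1 at 168 ± 103 and 62.1 ± 63.5 (2.02, limma adjusted p = 0.757) and PCNA1 (AT1G07370), a replication clamp gene, at 2.72 ± 4.71 and 22.1 ± 7.92 (−3.40, limma adjusted p = 0.698). Photosynthesis genes, with 0 called of 18, had a median of −0.56 and stood apart by camera (limma adjusted p = 4.64e-06), a call lost with an estimated correlation (adjusted p = 0.331 with an estimated correlation). PSBP-1 (AT1G06680), of photosystem II, was at 203 ± 141 in V-Mt and 331 ± 72.5 in WT.

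Each of the other 12 lists measured in microspores had 0 called members and did not pass by camera. Egg and central cell genes had no measured member. Adjusted over the list alone, 1 Polycomb gene rose (REF6) and 1 target factor fell (SEP2). Pollen tube genes passed without V-Mt LMS replicate 2 (limma adjusted p = 0.00117). Leaving out that library also called 2 genes, AT3G63052 and AT5G43695, named after their values were seen. Their means in V-Mt and WT were 450.7 and 705.9 FPKM for AT3G63052, and 79.08 and 239.6 FPKM for AT5G43695. Of 13849 loci tested in both tables, 8377 were higher and 1651 lower in V-Mt VC. With 0 genes called in microspores the overlap could only be 0, so it does not tell whether these loci change there. The all-gene median was −0.13, −0.04 with median-ratio scaling and 0.03 with quantile normalization.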

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

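The tests of genomic DNA, green tissue, sperm RNA carried into the VC sorts (for the genes that fell and for DAN1) and REF6 in V-Mt SC replicate 3 were chosen after the results they address were seen, while the GFP marker test and the splits of the libraries were set before. Of these, the tests of genomic DNA, green tissue and DAN1 each replaced an earlier test whose outcome was already known. The earlier DNA test was undecided: 17.5% of 4658 genes under 0.1 FPKM in WT VC were under 0.1 FPKM in V-Mt VC too, between its bounds. The earlier tissue test was undecided as well, with a photosynthesis median of 4.28 FPKM against 8.15 for the genes that rose and a bootstrap 95% interval of 1.78 to 11.6. The earlier DAN1 test was met, since DAN1 lay within the range of the other sperm-enriched genes, −8.26 to 0.042. All 3 replacements came out against the explanation, so they count for less than tests set beforehand.

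The V-Mt effect differed between vegetative and sperm nuclei, by a test of the difference itself, in 13351 genes. Camera (limma) compares a list with other genes. By that test the difference lay below that of other genes for pollen tube growth and signalling genes (adjusted p = 5.95e-17), sperm cell genes (0.0032) and vegetative cell wall and transporter genes (0.0032). With an estimated correlation the camera adjusted p was 0.000333, 0.318 and 0.326. Their median differences were −2.10, 0.12 and −0.19, against 2.24 over all genes. For sperm and wall genes camera thus does not show that the V-Mt effect differed between nuclei. The genes with the largest differences toward VC were AT1G67430 (log2 12.29), FKBP53 (12.08), UAP56b (11.83), AT5G61170 (11.53) and RPS15 (11.41), and REF6 differed by 8.05. Those with the largest differences the other way were ARLA1B (−8.74), AT1G11770 (−8.29), BSK8 (−7.94), AT1G21695 (−7.75) and SEC14 (−7.71). Groups held 3 libraries each, so the test of a single library's gap to the rest of its group was not run, and the effect of leaving out each library is given with the alternatives.

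V-Mt VC libraries held more genes at 1 FPKM or more than WT VC libraries, 18863 ± 111 against 8231 ± 147. Genomic DNA would cover silent genes alike, but among the 4658 long genes under 0.1 FPKM in WT VC the 75th percentile in V-Mt VC, 2.73 FPKM, was 16.7 times the 25th, which argues weakly against DNA as the whole source. A part from DNA stays open, since genes that rose above an even DNA level would widen this spread too. Of 2628 tested gene models without an AGI identifier 2214 rose and 99 fell, against 12334 rises among all 19733 genes. Whether DNA enters these models was not tested. RNA of green tissue, which the sort on nuclear GFP is meant to remove, would bring its abundant transcripts, but 0 of 18 photosynthesis genes lay above the 90th percentile (53.8 FPKM) of the genes that rose from under 1 FPKM, the highest at 29.2 FPKM, which argues weakly against it too. The GFP marker and gate cannot be told apart from the genotype, because 0 VC groups carry the marker of the other line. An effect of REF6 in the vegetative cell, the difference the design names, stays open and untested for that reason.

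Sperm cell genes fell and rose in V-Mt VC. For the 6 that fell, RNA of sperm nuclei carried into the VC sorts in differing amounts is a candidate explanation: WT VC held 0.965% to 4.15% of their WT SC level, with an interquartile range of 0.425 on the log2 scale, and V-Mt VC held 0.281% to 1.43% of their V-Mt SC level. For DAN1 the same source would need a like ratio, but its V-Mt VC level lay −2.10 from V-Mt SC on the log2 scale, against a median of −7.03 and an upper quartile of −5.93 for the 50 most abundant other sperm-enriched genes, 2 of which lay above DAN1. This argues weakly against carry-over as the whole source of DAN1. Expression of DAN1 in the vegetative cell of V-Mt stays open and was not tested apart from the marker.

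REF6 stood at 436.38 FPKM in V-Mt SC replicate 3, against 28.87 and 58.4 in the other V-Mt SC libraries. RNA of V-Mt VC nuclei carried into that sort would bring other VC transcripts at a like share, but 23 genes at 200 FPKM or more in V-Mt VC and under 1 FPKM in WT SC stood at a median of 0.721% of their V-Mt VC level there, against 20% for REF6. Of these 23 genes, 2 stood at or above the REF6 share. This argues against carry-over of VC RNA as the whole source, and other sources in this library were not tested.

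The libraries were also split in other ways. For V-Mt VC against WT VC 1 of 10 splits, the real one, called as many genes (14456, highest other 0), for WT SC against WT VC 1 of 10 (7981, highest other 15), and for V-Mt SC against V-Mt VC 1 of 10 (14090, highest other 0). For V-Mt SC against WT SC 2 of 10 splits called as many (1008, highest other 1077), and for microspores 10 of 10 (0, highest other 2). These splits are too few for a share under 0.05. The split with 1077 calls followed the organelle share of the sperm libraries, so it points to a structure of the samples other than their group. For the interaction 1 of 100 drawn splits, the real one, called as many (13351). The highest other count, 12091, came from 1 of the 8 drawn splits that left the VC labels in place, and with those labels changed the highest was 0. The count thus rests on the VC labels, and these splits do not test whether the V-Mt effect differed between VC and SC.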

How the results depend on the processing

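The term for, and the fits without, the libraries with a high organelle share and the block within each line were chosen after the data were seen; all other alternatives were planned. Counts over all alternatives were 10957 to 17420 genes for V-Mt VC against WT VC, 6463 to 8950 for WT SC against WT VC, 10742 to 16893 for V-Mt SC against V-Mt VC and 8994 to 15160 for the interaction, each within 1.5 times the reported count. V-Mt SC against WT SC moved from 1008 to 612 without a filter, 430 with quantile normalization, 34 with array weights and 0 with only the 2 groups compared (fewer samples for the spread), and 322 to 3296 when 1 library was left out. It was 347, 322 and 379 without V-Mt VC replicates 1, 2 and 3, 390 and 384 without WT VC replicates 2 and 3, 517 without WT SC replicate 1 and 3296 without WT SC replicate 3. Microspores went from 0 to 2 genes without V-Mt LMS replicate 2 (0 to 2 over left-out libraries). Of 83 list tests 18 passed, 8 with an estimated correlation (all among the 18), 49 with fry, which does not compare a list with other genes, 24 with median-ratio scaling (the 18 and 6 more), 19 with a pseudocount of 0.1 and 17 to 22 with 1 library left out. List tests were not run with quantile normalization, where the counts of members give the comparison. The marker score differences kept their sign, and 59.9% to 76.1% of WT sperm-enriched genes rose and 45.3% to 61.5% of WT VC-enriched genes fell. The cause of these shifts was not tested, except where fewer samples enter.

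Taken over all groups, few same-numbered samples paired: of 21 same-numbered pairs 2 had a correlation of deviations above 0.1 (−0.201 to 0.145), and 6 of 21 correlated best with their own number. The 21 pairs include the 6 of VC and SC of 1 line. Of these 6, 5 correlated best with their own number (−0.064 to 0.145, 2 above 0.1). This is a hint of pairing within a line, from the data and not from the design. With the replicate number as a block, V-Mt SC against WT SC called 608 genes, and the number of list tests that passed was 18. A block within each line called 7634 genes for WT SC against WT VC, 14005 for V-Mt SC against V-Mt VC and 13164 for the interaction, and changed no list call in these.

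With fry the direction reversed for 14 list tests, as it tests movement on balance and not relative to other genes. In V-Mt VC against WT VC these were cell cycle (adjusted p = 1.53e-05), sperm (0.0433) and tapetum genes (1.89e-05), and in WT SC against WT VC the Polycomb targets (0.00216). In V-Mt SC against V-Mt VC they were histone (0.00422), microspore (0.000532), photosynthesis (0.00107) and pollen MADS, MYB and WRKY genes (3.32e-05). For the interaction they were cell cycle (0.000115), microspore (0.0275), MADS, MYB and WRKY (0.016), sperm (0.229), tapetum (0.000399) and vegetative wall genes (0.645). With median-ratio scaling MGH3 in VC turned to −0.23 and WRKY2 in the interaction to −0.86. With quantile normalization GCS1 (−0.22), EC1.2 (−0.26) and MGH3 (−0.21) turned in VC, and GCS1 (−0.64) and LBD27 (−0.43) in the interaction; the cause was not tested. Of the values of 342 named gene results under other settings, 3077 stayed on their side, 205 lost and 11 gained a call, and with 1 library left out 3710, 211 and 9. In microspores, the libraries with the lowest estimated depth (1900000 to 3100000 fragments), 32% of simulated changes of 4 on the log2 scale were recovered, against 80% for V-Mt VC against WT VC, so a count of 0 there does not show an absence of changes. Whether depth or the spread between replicates set that share was not tested.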

Other observations

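The tests of protein families and of microspore transcripts were chosen after the results were seen, while the test of a sperm-like transcript set was written before. Among 481 protein domain families tested in V-Mt VC against WT VC, 1 was called higher and 49 lower than other genes by camera (limma). Class II aminoacyl-tRNA synthetases, which charge tRNAs, had 21 rising and 0 falling members of 22 (median 4.53, adjusted p = 0.0164, and adjusted p = 0.554 with an estimated correlation). Proteasome alpha and beta subunits had 21 and 0 of 24 (median 5.80) without passing (adjusted p = 0.0986). Pectinesterase inhibitor genes had 16 rising and 23 falling members of 59 (median −0.55, adjusted p = 3.8e-07, and 0.22 with an estimated correlation), and PLC-like phosphodiesterases 6 and 10 of 18 (median −2.49, adjusted p = 3.08e-05, and 0.345 with an estimated correlation). Kinesin motor genes had 14 and 18 of 46 (median −0.12, adjusted p = 2.46e-05, and 0.355 with an estimated correlation).

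In WT SC against WT VC, 18 families were called higher and 11 lower by camera (limma). Core histone genes had 27 rising and 3 falling members of 45 (median 2.67, adjusted p = 0.00718) and HMG box genes, which encode chromatin proteins, 12 and 0 of 16 (median 2.94, adjusted p = 0.00813). Cation/H+ exchanger genes had 6 and 16 of 36 (median −0.92, adjusted p = 0.0119). All 3 missed with an estimated correlation (adjusted p = 0.755, 0.673 and 0.673). In V-Mt SC against WT SC no family was called. In microspores 0 of 483 were called higher and 6 lower, among them the chlorophyll a-b binding proteins (21 members, median −0.57, adjusted p = 0.00266) and the aquaporins (19 members, median −1.18, adjusted p = 0.0274), both at 0.88 with an estimated correlation and with 0 genes called.

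A hypothesis is that V-Mt VC holds transcripts that the late microspore also holds. Among nuclear genes under 1 FPKM in WT VC, tested without a filter on low values, 71.3% of the 6452 at 10 FPKM or more in WT LMS rose in V-Mt VC, against 49.7% of the 2020 under 1 FPKM in WT LMS. The difference of 21.6 percentage points lay above the 10 set for the test, which is consistent with the hypothesis. It replaced a first computation, whose outcome was known, over genes past the filter (83.7% of 4894 against 70.1% of 778, a difference of 13.6), since genes low in WT VC can pass that filter through V-Mt VC alone. Genes abundant in microspores may be abundant in many tissues, which was not tested, and their levels come from a separately normalized table. In WT LMS the 18 photosynthesis genes had a median of 514 FPKM, and chloroplast and mitochondrial genes took 6.38% to 6.48% of FPKM. Whether RNA of green tissue enters these microspore levels was not tested. A second hypothesis, that V-Mt VC gained a sperm-like transcript set, was tested on sperm-enriched genes. Of the 246 under 1 FPKM in WT LMS 40.7% rose, against 76.2% of the 3617 at 10 FPKM or more. This difference of −35.5 percentage points lay past the 10 set as the bar against the hypothesis. Among all genes low in WT VC, those low in WT LMS also rose less often. The test therefore cannot decide for or against a gain of sperm transcripts as a set.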
